A study of Mus musculus with 2 samples.

How the data were processed

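Skin of mice injected with sitagliptin in PBS or with PBS alone was profiled with 10x Genomics Chromium single-cell RNA sequencing of polyadenylated RNA, 1 library per treatment. Cell Ranger 3.1.0 and the mm10 genome are named in the submitters' processing notes. The values used are counts of UMIs per gene and barcode, not normalized, as the authors deposited them, with 31053 genes in each library, per the file headers. How barcodes were called as cells and whether libraries were made on 1 day is not given in the sources used here. The lowest total was 500 UMIs per barcode in the PBS-labelled and 1138 in the sitagliptin-labelled library, and 75 barcodes occurred in both. Groups follow the titles and treatment labels. A letter in the name of each library's files is the initial of the other treatment, which is why the text speaks of labelled libraries.

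The filters, clustering settings, marker lists, gene lists, size rule and alternatives, apart from those said below to be later, were fixed before the data were examined. Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Scrublet in scanpy 1.11.5 called 2 of 5932 and 0 of 18380 cells as doublets, too few for the caller to have worked, so doublets remain among the cells and removal of the 8% of cells with the highest scores was added as an alternative. Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together without alignment on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15, seed 1). Figures were drawn with matplotlib 3.10.9.

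Clusters were named by the class whose markers had the highest mean score, from 22 marker lists. A cluster stayed unnamed if its score led the second class by under 0.1, or if a second class of another broad type reached over 0.6 of it. It also did if fewer than 3 markers were detected in at least 10% of cells. So did a cluster where markers of another class outnumbered its own among its 10 leading genes, or those of another broad type at least equalled them. The last rule was for clusters without an own marker there, where the library median of UMIs was over 3 times theirs. These thresholds were tightened after the data were examined and left 2.31% of retained cells in the PBS-labelled and 41.9% in the sitagliptin-labelled library without a class. Shares have exact Clopper-Pearson 95% intervals, and a share of 0 has the limit that 3 counts allow. For levels, UMIs were summed per library and class, in classes with at least 50 cells in each library, and given as CPM with the exact conditional binomial interval of the ratio. Retained cells held 57127917 and 85056939 UMIs, and class totals ran from 2496629 UMIs in outer root sheath or bulge cells of the PBS-labelled library to 36267763 in suprabasal cells of the other, so genes of low level have wide intervals. These intervals hold no variation between animals or preparations.

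The rule for named genes took classes with at least 200 cells in both libraries and genes with at least 50 CPM in either library and 20 UMIs in all. It left out mitochondrial, ribosomal, haemoglobin, sex-linked, immunoglobulin, T cell receptor, predicted and dissociation genes, and genes over 10 times higher in another class, which free RNA could carry. Up to 12 genes each way at least 1.5-fold apart were named in the 3 largest classes and up to 4 in the last; a condition on the same direction in both sexes was dropped, as too few cells carried Y-linked transcripts. Dpp4 and the members of each list with the largest and smallest ratios, dissociation and mitochondrial lists included, could be named besides, and some genes that meet these rules are not reported here. The size rule counted genes at least 2-fold apart. Lists used a pseudocount of 1 CPM and members with at least 20 UMIs; 27 lists were fixed, and the symbols Ccn1, Ccn2, Cxcl11, Il36g, Krt85 were not found. The X inactivation and Y-linked lists served the comparison of sexes alone. Coordinates are from GENCODE vM21 on mm10, in which 30934 of 31053 gene identifiers (99.6%) matched, and 31-base words at annotated 3' ends were compared between genes to find reads that copies could share.

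The level and list steps were tested on simulated data drawn from the real class means with 200 genes altered per class, 50 at each fold. Genes altered 3-fold were past the 2-fold rule in 100% of cases in each of the 4 classes, genes altered 2-fold in 42% in basal, suprabasal and upper follicle and 40% in outer root sheath or bulge cells, and genes altered 1.5-fold in 0%. No unaltered gene was past the rule, among 2771 in basal, 2711 in suprabasal, 2771 in upper follicle and 2877 in outer root sheath or bulge cells. Both simulated libraries were drawn from the same pooled class mean with counting error alone. The simulation therefore cannot show how often animals, preparations, free RNA, doublets or cluster makeup put a gene past the rule. The alternatives tried were mitochondrial limits of 5% and 20%, at least 1000 genes and 2000 UMIs, doublets kept, Leiden resolutions of 0.5 and 2, each library scaled on its own, shares within the broad class, cells with Xist alone, TMM scaling, totals without mitochondrial, ribosomal and haemoglobin genes, the mean of each cell's CPM, cells thinned to 1000 UMIs, free RNA subtracted at 5% of each total, a minimum of 10 CPM, a 3-fold rule, a pseudocount of 10 CPM, list members with at least 100 UMIs, and for dividing cells no thinning or a single gene. Chosen after the data were examined were at least 3000 UMIs, removal of the highest doublet scores, and equal weight for each cluster with at least 30 cells in both libraries. Free RNA was subtracted for the ratios of single genes alone, not for lists or counts of genes. The 3 scalings moved the median log2 ratio of a class by at most 0.041 upwards and -0.063 downwards.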

Results

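Single-cell RNA profiles were collected from mouse skin after intradermal injection of sitagliptin, an inhibitor of dipeptidyl peptidase 4 (DPP4), or of phosphate-buffered saline (PBS) alone. DPP4 is a cell-surface serine protease that removes dipeptides from the N-terminus of peptide hormones, growth factors and chemokines, and the title of the series places the work in hair follicle activation and regeneration. The mice were C57Bl6 animals of 8 weeks and, by the labels, male and female; the dose was 100 ng in 100 µl, and a time of 48 h is named beside the processing of the skin, without saying from which event it runs. There was 1 library for each treatment, so there are no replicates, no test was made, and every interval below is a 95% interval that covers counting error only. The PBS-labelled library held 10456 barcodes and 70729930 unique molecular identifiers (UMIs), with a median of 4206 per barcode. The sitagliptin-labelled library held 22085 barcodes and 95047000 UMIs, with a median of 2108. After filtering, 5930 cells (56.7%) with a median of 6900.5 UMIs and 18380 cells (83.2%) with a median of 2197 UMIs were retained. A letter in the name under which each library was deposited is the initial of the other treatment; an exchange of the labels cannot be excluded from the sources used here, and it would turn every direction given below.

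The first comparison asked whether the cell types of the skin were present in different proportions after sitagliptin. Fibroblasts, macrophages, lymphocytes and muscle cells made up a sizeable part of the PBS-labelled library and almost none of the sitagliptin-labelled one. Class names stand for cells resembling the named type by marker genes. Fibroblast-like cells, led by the collagen genes Col1a2 and Col3a1, were 7.94% (471 of 5930 cells, 7.27 to 8.66) of the PBS-labelled library and 0.0490% (9 of 18380 cells, 0.0224 to 0.0929) of the sitagliptin-labelled library, a share lower by 162-fold. Macrophage-like or monocyte-like cells, marked by the complement genes C1qa, C1qb and C1qc or by Lyz2, were 17.4% (1030 of 5930 cells, 16.4 to 18.4) against 0.169% (31 of 18380 cells, 0.115 to 0.239), lower by 103-fold. T cells or innate lymphoid cells were 1.53% against 0.109%, dendritic cells 1.45% against 0.223%, and lymphatic endothelial cells 0.826% against 0.0272%. Blood endothelial cells were closer, at 0.607% and 0.25%. Skeletal muscle cells were 54 of 5930 cells (0.911%) in the PBS-labelled library and 0 of 18380 in the other, which allows a share of up to 0.0163%. Myeloid classes together were lower by 48.0-fold, at 18.8% against 0.392%. The 2 libraries also differed in barcodes over the mitochondrial limit, 39.9% in the PBS-labelled and 16.8% in the sitagliptin-labelled one, in retained cells under 2000 UMIs, 8.31% and 44.5%, and in retained cells left without a class, 2.31% and 41.9%. Over the alternative settings the ratio of fibroblast shares, 0.00616 as given, reached 0.0864 with the genes of each library scaled separately, and the ratio for macrophages, 0.00971, reached 0.467 within the myeloid cells.

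**Figure D1:**
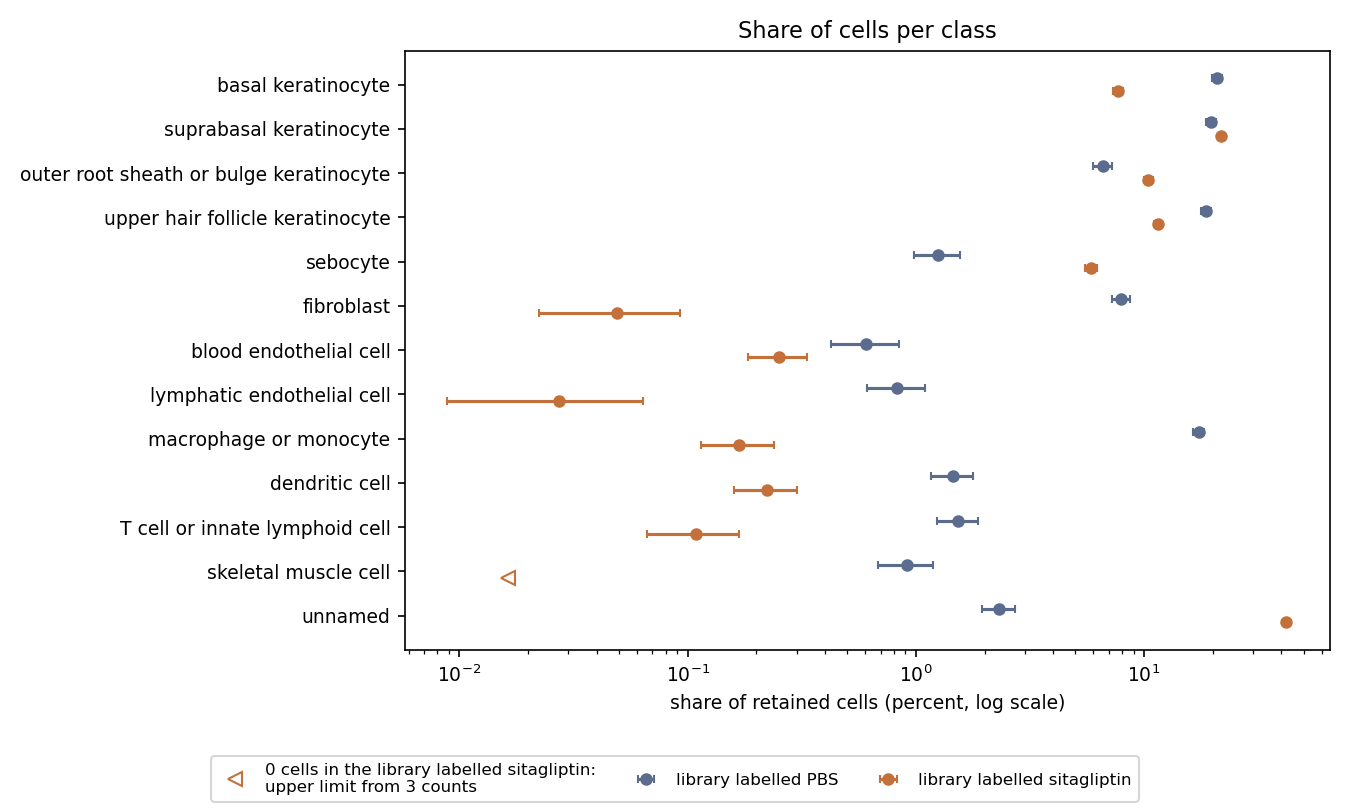
Share of retained cells in each class (percent, log axis) in the PBS-labelled library (5930 cells) and the sitagliptin-labelled library (18380 cells), 1 library each; points are shares and bars exact binomial 95% intervals for counting error. Fibroblasts stand at 7.94% against 0.0490% and sebocytes at 1.25% against 5.87%.

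Keratinocytes, the epithelial cells of epidermis and follicle, were 67.0% of the PBS-labelled library and 57.3% of the sitagliptin-labelled library, by named cells. The second value leaves out a cluster of 7631 sitagliptin-labelled cells (41.5%), unnamed because 2 keratinocyte classes scored alike, upper follicle at 0.449 and suprabasal at 0.444. The direction turned under 7 of 9 settings, to 67.8% against 98.9% at a Leiden resolution of 0.5. The lower share of named cells is therefore not read as a lower share of keratinocytes. The makeup of the named keratinocytes differed. Basal keratinocytes, the Krt5 and Krt14 layer that renews the epidermis, were 20.8% against 7.71%, a ratio of 0.370 (0.343 to 0.400). With at most 5% mitochondrial UMIs an unnamed cluster of 19 and 1786 cells scored 0.211 for upper follicle and 0.201 for basal cells. Basal cells among the unnamed ones are therefore not excluded, and the interval does not cover this. Keratinocytes of the outer root sheath or bulge, the follicle compartment that holds stem cells, were 6.59% against 10.4%, a ratio of 1.58 (1.42 to 1.77). Sebocytes, the lipid-producing cells of the sebaceous gland, were 1.25% against 5.87%, a ratio of 4.70 (3.72 to 6.04). This higher share came from a cluster of 13 and 1003 cells with a sebocyte score of 1.23 and, in the sitagliptin-labelled library, a median of 1740 UMIs. The cluster with the stronger score, 3.58, held 61 of 5930 and 76 of 18380 cells, a lower share in the sitagliptin-labelled library. Suprabasal keratinocytes were 19.7% against 21.8% and upper follicle keratinocytes 18.7% against 11.5%. Counted among named keratinocytes alone, basal cells were 31.1% against 13.5%, outer root sheath or bulge cells 9.83% against 18.2%, sebocytes 1.86% against 10.2% and suprabasal cells 29.3% against 38.1%. Upper follicle cells were 27.9% against 20% of keratinocytes. The direction of their share of all retained cells, 18.7% against 11.5%, turned under 6 alternative settings, to ratios of 1.47 to 2.79. The other ratios of shares of retained cells kept their direction, with values of up to 0.626 for basal and 1.02 to 1.98 for suprabasal cells. They were 1.06 to 5.09 for outer root sheath or bulge cells and 1.58 to 16.9 for sebocytes, lowest with at least 3000 UMIs per cell. Among keratinocytes the suprabasal direction turned with each library scaled on its own, where the ratio was 1.02 for suprabasal cells and 1.36 for all named keratinocytes.

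Gene levels were then compared within each keratinocyte class, to ask how the cells that build epidermis and follicle differed after sitagliptin. Levels are UMIs summed over a class and scaled to its total (CPM), with the sitagliptin-labelled library first and the ratio to the PBS-labelled library. In basal keratinocytes the wound-associated keratins Krt16 and Krt6a were lower, and Zbtb16 and Tsc22d3 were higher. Krt16 was lower (2.47-fold, 2.24 to 2.73, 62.4 against 155 CPM), as was Krt6a (2.15-fold, 2.04 to 2.26, 253 against 543 CPM), both keratins of activated and wounded epidermis. Zbtb16, a zinc finger repressor that glucocorticoids induce, was higher (2.71-fold, 2.46 to 2.99, 139.9 against 51.6 CPM), and so was Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (2.13-fold, 1.91 to 2.36, 103 against 48.3 CPM). Also higher were Defb1, a beta-defensin of epithelia (2.61-fold), Nmt1, which attaches myristate to proteins (2.52-fold), its paralogue Nmt2 (1.89-fold), the metal ion transporter Slc39a8 (2.26-fold) and the dynein intermediate chain gene Dync1i2 (2.23-fold). The drug efflux pump gene Abcb1b was higher by 1.91-fold, the antiproliferative gene Btg1 by 1.90-fold, the amino acid transporter gene Slc38a2 by 1.89-fold, and Nifk and Tex10 by 1.92- and 1.87-fold. Lower were Gsta4, a glutathione transferase gene (2.0-fold), the matricellular gene Cyr61 (1.75-fold), the EGF receptor ligand gene Hbegf (1.53-fold), the transcription factor gene Stat3 (1.51-fold) and the glycolytic enzyme gene Eno1 (1.51-fold), together with Erh and Sap18 (1.64- and 1.60-fold). The stefin A genes Stfa1 and BC100530 were lower by 1.82- and 1.53-fold, but 45.9% and 44.9% of the 31-base words at their 3' ends occur in other genes, so the split of reads between such copies is uncertain. Of 3106 genes with at least 50 CPM in a library and 20 UMIs in all, 9 were at least 2-fold higher and 4 at least 2-fold lower, and 97.6% lay within 1.5-fold. Gsta4 came closer to equal when cells were thinned to 1000 UMIs, at a ratio of 0.782.

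Suprabasal keratinocytes, the differentiating layers, had the wound keratins Krt6b, Krt6a and Krt16 lower too. Krt6b was lower by 7.74-fold (7.01 to 8.56, 14.2 against 109.9 CPM), Krt6a by 2.91-fold (2.79 to 3.03, 118 against 343 CPM), and Krt16 by 2.48-fold (2.40 to 2.56, 191 against 473 CPM). Krt6b (ENSMUSG00000023041; chromosome 15, 101676023 to 101680287, mm10) and Krt6a (chromosome 15, 101689910 to 101694307) are neighbouring paralogues whose 3' ends can be told apart, with 1.28% and 0% of 31-base words found in another gene, against 32.6% for Krt16. Hbegf was lower by 1.80-fold, the cornified envelope gene Sprr1b by 1.54-fold and Eno1 by 1.75-fold, while Ereg, which encodes another EGF receptor ligand, was higher (2.30-fold, 2.07 to 2.55, 61.8 against 26.9 CPM). Sap18 and Tiparp were lower by 1.69- and 1.52-fold, and the stefin genes BC100530 and Stfa1, with shared 3' ends as above, by 2.09- and 1.75-fold. Among the genes with at least 50 CPM in a library that were open to naming, the highest ratio was that of Nmt1 (2.35-fold, 2.23 to 2.49, 221 against 93.9 CPM; chromosome 11, 103028190 to 103068912), and Nmt2 was higher by 1.98-fold. Zbtb16 was higher by 2.13-fold, Txnip, an inhibitor of thioredoxin, by 2.10-fold, Dync1i2 by 2.11-fold, the aldehyde dehydrogenase gene Aldh3a1 by 1.89-fold and Btg1 by 1.87-fold. Ppp2r3a, Nifk, Fxr1 and Tuba1c, which encode a phosphatase subunit, a nucleolar protein, an RNA-binding protein and a tubulin (44.1% of 3' end words shared), were higher by 1.92-, 1.89-, 1.89- and 1.89-fold. Among 3027 genes 8 were at least 2-fold higher and 7 at least 2-fold lower, with 97.4% within 1.5-fold. The largest cluster of the class was an early one led by Krt1 and Mt4 in the PBS-labelled library (593 and 715 cells in the PBS-labelled and the sitagliptin-labelled library) and a late one led by Lor and Flg2 in the other (62 and 1946 cells). With clusters weighted equally Krt6b was lower by 4.44-fold, and 7 genes in place of 15 were at least 2-fold apart, but other settings gave more, 34 with doublets kept, 34 by the mean of each cell's CPM, 38 without the highest doublet scores and 45 with cells thinned to 1000 UMIs. A suprabasal cluster led by Krt16, with Krt6a, Stfa1 and Sprr1b among its leading genes, stood apart at a Leiden resolution of 2. It held 122 of 5930 PBS-labelled and 83 of 18380 sitagliptin-labelled cells. This difference in makeup stays open as a part of the lower wound keratins.

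In upper follicle keratinocytes, which line the opening and isthmus of the follicle, the glucocorticoid-induced genes Tsc22d3, Fkbp5 and Ddit4 were among those higher. Tsc22d3 was higher by 2.68-fold (2.49 to 2.89, 192 against 71.9 CPM), and Fkbp5, a co-chaperone of the glucocorticoid receptor, by 2.17-fold (1.98 to 2.38, 109 against 50.2 CPM). Ddit4, an inhibitor of mTORC1 that stress and glucocorticoids induce, was higher by 2.05-fold. Nmt1 was higher by 2.32-fold (2.17 to 2.48, 221 against 95 CPM), Nifk by 2.09-fold, the corepressor gene Tle4 by 1.99-fold, Dync1i2 and Tex10 by 1.88- and 1.89-fold, Btg1 by 1.86-fold and Txnip by 1.85-fold. The long intergenic RNA AC160336.1 (chromosome 14, 44544055 to 44637201) was higher by 2.70-fold. Lower among the genes open to naming, which leave out ribosomal and dissociation genes, were Erh, Eno1 and Hbegf, by 1.80-, 1.70- and 1.70-fold. Of their 3' end words 28.9%, 19.9% and 0% occur in another gene. Of 3111 genes 8 were at least 2-fold higher and 1 at least 2-fold lower, and 98.2% lay within 1.5-fold. The 9 genes past 2-fold became 33 with doublets kept, 17 with at least 1000 genes and 2000 UMIs per cell and 15 when thinned.

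Outer root sheath or bulge keratinocytes had the most genes at least 2-fold apart among these 4 classes, except without the 8% highest doublet scores (37 against 38 in suprabasal cells), and their clusters were unevenly filled. Angptl7, a secreted angiopoietin-like protein gene, was higher by 3.16-fold (2.52 to 4.01, 105 against 33.2 CPM), and Fam46b, a poly(A) polymerase gene, by 2.62-fold. Gjb2, a gap junction gene of activated epidermis, was lower by 21.0-fold (12.9 to 36.0, 2.42 against 50.9 CPM). Nrp2, a semaphorin and VEGF co-receptor gene, was lower by 3.95-fold, and Dct, a melanin synthesis gene of melanocytes, by 6.55-fold. Arg1 and Krt75 (145 against 37.2 and 370.1 against 96.9 CPM) lead a cluster with 37 and 415 cells, Slc7a2 (30.5 against 104 CPM) leads one with 112 and 177 cells, clusters that were filled unevenly. Over all settings tried Arg1 and Krt75 stayed higher by at least 1.79- and 1.55-fold, while Slc7a2 turned, to a ratio of at most 1.20. Of 3329 genes 29 were at least 2-fold higher and 35 at least 2-fold lower; without mitochondrial, ribosomal and haemoglobin genes in the total these were 25 and 52. With at least 1000 genes and 2000 UMIs per cell Dct and Nrp2 turned, to ratios of 2.01 and 3.63, and Nrp2 did so with at least 3000 UMIs (3.06) as well. Under every setting run Gjb2 stayed lower by at least 2.13-fold, Angptl7 higher by at least 1.94-fold and Fam46b by at least 1.32-fold. In sebocytes, held mostly by a cluster with 61 and 76 cells in the PBS-labelled library and by one with 13 and 1003 cells in the other, 272 and 100 of 3514 genes were past 2-fold and no gene is read.

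**Figure D2:**
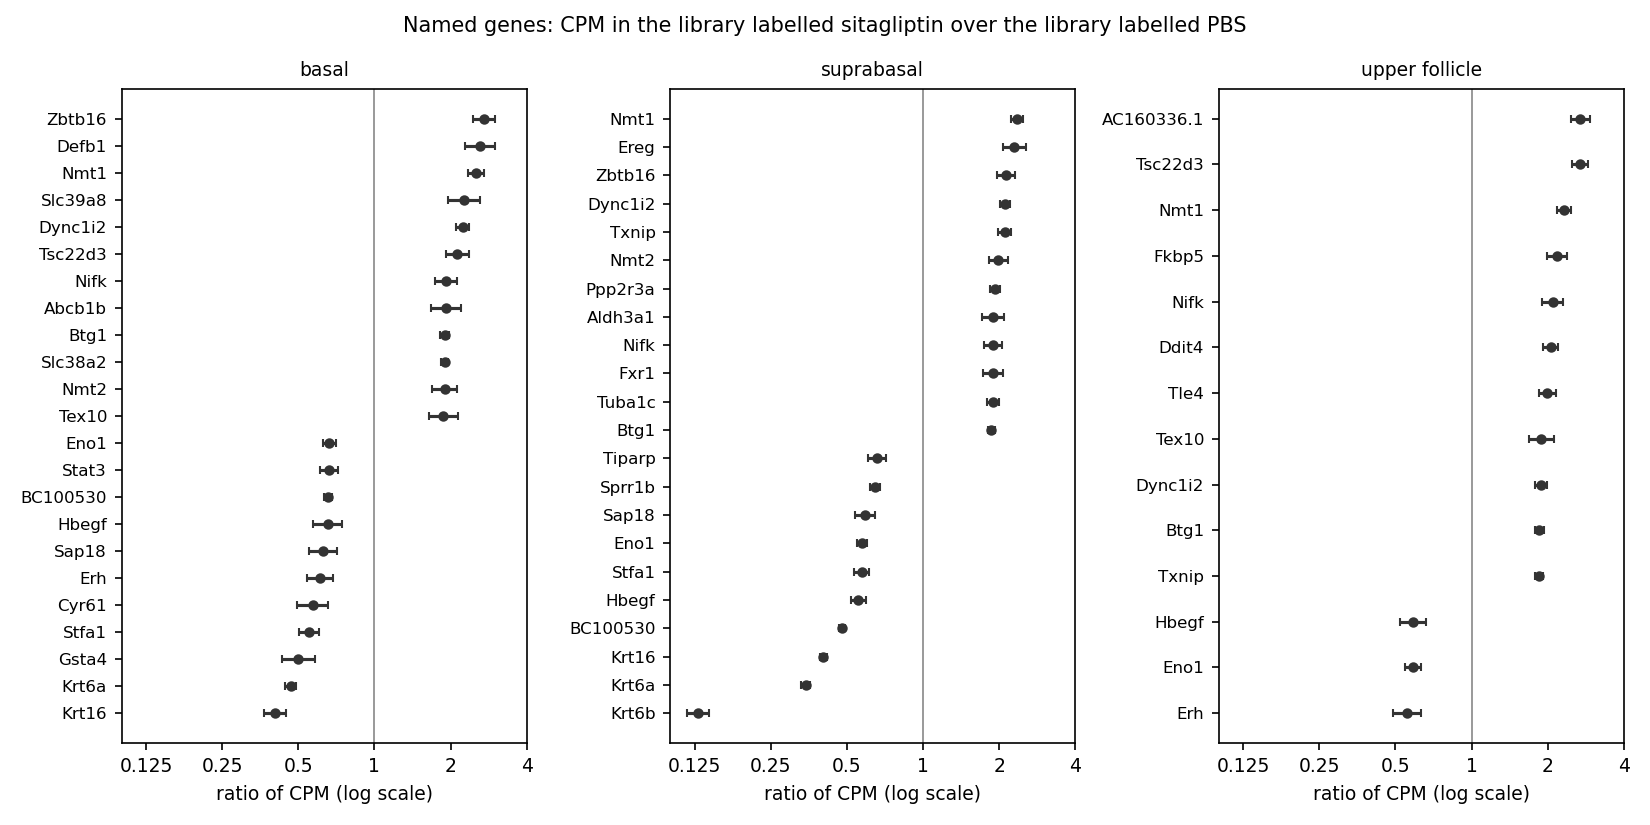
Ratio of CPM, sitagliptin-labelled over PBS-labelled library (log axis), for the genes named in basal, suprabasal and upper follicle keratinocytes; points are ratios from 1 library per treatment and bars exact conditional binomial 95% intervals for counting error. Krt6b stands at 0.129 in suprabasal cells and Zbtb16 at 2.71 in basal cells.

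Gene lists fixed before the data were examined were compared by the median log2 ratio of their measured members and its percentile among 10000 random lists matched on expression, a description of these 2 libraries. Values are given for basal, suprabasal, upper follicle, and outer root sheath or bulge keratinocytes in that order. Wound and stress genes had medians of -0.73, -0.37, -0.24 and -0.15 (percentiles 0, 0, 0.0400 and 10.7). In basal cells 10 of 18 members were at least 1.5-fold lower and 1 higher, with Krt6b at 1.70 against 40.5 CPM and the small proline-rich gene Sprr2a3 at 4.73 against 22.7 CPM, while Ereg and Tgfa, growth factor genes, stood at 3.27 against 1.04 and 20 against 13.3 CPM. In suprabasal cells 8 of 21 were lower and 3 higher, where the cluster led by Krt16 described above leaves makeup open. The interferon response list had medians of -0.42, -0.44, -0.40 and -0.71 (percentiles 0, 0, 0 and 0), with 7 members lower and 0 higher in each class; Ifi27l2a was 14.7 against 36.8 CPM in suprabasal cells and the chemokine gene Cxcl9 1.34 against 5.81 CPM in upper follicle cells. Transcripts of immune and dermal cells were lower in the same keratinocytes: Lyz2, a macrophage gene, was 0.485 against 22.7 CPM and Col3a1 0.485 against 13.3 CPM in basal keratinocytes. Macrophage genes themselves had medians of -2.66, -2.41, -2.16 and -3.09 in keratinocytes (percentiles 0, 0, 0 and 0), led by Retnla at 0.485 against 24.8 CPM in basal cells. The MHC class II list had medians of -1.0, 0.085, -0.42 and -1.17 (percentiles 0, 62.6, 0 and 0), with Cd74 at 14.7 against 35.4 CPM in basal cells, and the extracellular matrix list -0.10, 0.066, -0.25 and -0.24 (percentiles 8.32, 64.3, 0 and 0.0300), with Col1a1 at 0.727 against 8.76 CPM and Sparc at 192 against 136 CPM in basal cells. Immediate early and heat shock genes, which tissue dissociation induces, had medians of -0.18, -0.37, -0.12 and -0.71 (percentiles 0, 0, 0 and 0), with 4, 9, 4 and 16 of 28 lower; Atf3 was 36.3 against 74.0 CPM and Nr4a1 13.3 against 28.6 CPM in suprabasal cells. The wound list turned in upper follicle cells under 3 settings, to at most 0.18. With members of at least 100 UMIs the outer root sheath or bulge medians turned to 0.15 for macrophage and 0.17 for extracellular matrix genes.

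Hair follicle stem cell genes were higher in the basal and suprabasal classes, with list medians of 0.34, 0.55, 0.14 and 0.041 (percentiles 100, 100, 99.8 and 72.4) in the same order of classes. In suprabasal cells 9 of 19 members were at least 1.5-fold higher and 0 lower, with the bulge regulator Lhx2 at 12.5 against 2.29 CPM and Tbx1 at 5.98 against 0.930 CPM; in basal cells 7 of 18 were higher, with Lgr5, a Wnt-responsive stem cell gene, at 5.82 against 1.45 CPM and Lhx2 at 16.9 against 5.62 CPM. Outer root sheath or bulge cells, whose own genes these are, had Cd34 at 336 against 255 CPM and Cdh3 at 46.3 against 90.1 CPM, and were a larger share of the sitagliptin-labelled library. No free RNA was subtracted for lists, so free RNA or doublets from those cells stay open as a part of the higher medians. The differentiation list had medians of 0.45, 0.19, 0.039 and 0.82 (percentiles 100, 100.0, 89.8 and 100), with 17 of 23 members higher in outer root sheath or bulge cells, among them the cornified envelope gene Lce1m at 18.6 against 2.40 CPM and Flg2 at 28.0 against 8.01 CPM. Cell cycle genes had medians of 0.11, 0.42, 0.042 and -0.060 (percentiles 99.9, 100, 95.8 and 25.5), with 7 of 32 higher in suprabasal cells, where the G1/S cyclin gene Ccne2 was 12.5 against 4.96 CPM and Top2a 174 against 99.2 CPM. Secreted or membrane Wnt inhibitors had medians of 0.49, 0.70, 0.10 and 0.29 (percentiles 99.9, 100, 88.0 and 97.4), with Dkk3 at 7.22 against 2.85 CPM and Sostdc1 at 66.9 against 37.9 CPM in suprabasal cells. Wnt targets and ligands stood near 0 in the first 3 classes and lower in the last, at -0.046, 0.019, 0.011 and -0.39 (percentiles 14.5, 38.3, 60.3 and 0), with Lef1 at 8.54 against 28.8 CPM in outer root sheath or bulge cells. Hair-inductive growth factors had medians of 0.44, 0.45, 0.11 and -0.65 (percentiles 100.0, 100, 90.4 and 0), with follistatin (Fst) at 16.2 against 4.90 CPM in suprabasal and Tgfb2 at 25.5 against 53.7 CPM in outer root sheath or bulge cells. An outer root sheath or bulge cluster with Lgr5 and Pdgfa among its leading genes held 112 of 391 PBS-labelled and 177 of 1918 sitagliptin-labelled cells. Such a difference in makeup stays open as a part of the lower Wnt and growth factor medians in that class. Over the settings tried, the stem cell median in suprabasal cells ran from 0.31 to 1.30 and in basal cells from 0.015 to 0.41. The cell cycle median in suprabasal cells ran from 0.10 to 1.15. Both signs were taken in upper follicle cells by the cell cycle (-0.32 to 0.12) and differentiation medians (-0.16 to 0.80), and in outer root sheath or bulge cells by the stem cell (-0.20 to 0.14) and cell cycle medians (-0.62 to 0.43).

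The remaining lists lay closer to 0 in most classes. Medians, in the same order of classes, were 0.019, 0.17, 0.11 and 0.092 (percentiles 52.8, 98.0, 95.6 and 86.5) for the BMP pathway, 0.20, 0.17, 0.092 and -0.44 (percentiles 95.7, 89.6, 83.0 and 0.0300) for the Hedgehog pathway, and 0.13, -0.12, -0.16 and -0.079 (percentiles 83.5, 7.86, 7.0 and 38.1) for hair shaft and inner root sheath genes. In outer root sheath or bulge cells Bmp2, which marks the cluster with Krt75, was 152 against 59.7 CPM. The myofibroblast and TGF-beta response list had medians of 0.014, 0.083, 0.022 and -0.40 (percentiles 61.5, 74.3, 69.7 and 0), yet its members parted: Ctgf, a matricellular target of TGF-beta, was 18.8 against 2.41 CPM in basal and 13.6 against 2.60 CPM in suprabasal cells, while Cyr61 was 9.60 against 21.1 CPM in suprabasal cells. Inflammatory cytokines had medians of -0.19, -0.13, 0.025 and -0.018 (percentiles 3.31, 0.850, 61.5 and 26.7), with the chemokine gene Ccl20 at 16.1 against 28.6 CPM in suprabasal cells, and the adventitial fibroblast list -0.14, -0.16, -0.18 and 0.023 (percentiles 10.5, 0.645, 3.61 and 57.9). Hypoxia and glycolysis genes had medians of 0.074, 0.022, -0.059 and 0.044 (percentiles 95.9, 46.6, 13.5 and 72.9), and cholesterol and fatty acid synthesis genes -0.054, -0.028, -0.076 and -0.27 (percentiles 7.93, 5.53, 4.12 and 0.0100), with the sterol-regulated gene Insig1 at 7.14 against 24.8 CPM in outer root sheath or bulge cells. Nuclear-encoded oxidative phosphorylation genes had medians of -0.064, -0.086, -0.032 and -0.054 (percentiles 18.5, 3.81, 38.3 and 23.2). The mitochondrially encoded list had medians of -0.0066, -0.041, 0.016 and -0.093 (percentiles 68.7, 47.8, 80.9 and 27.6), although mt-Atp8, an ATP synthase subunit gene, was 224 against 93.3 CPM in basal and 268 against 115 CPM in upper follicle cells. The angiogenesis list, with 3 to 5 measured members, had medians of 0.052, -0.094, -0.092 and -0.73 (percentiles 69.1, 11, 26.2 and 0.205). In outer root sheath or bulge cells the Hedgehog median turned to 0.062 with at least 1000 genes and 2000 UMIs per cell and to 0.038 with clusters weighted equally, and the angiogenesis median to 0.0091 in the first of these settings. With members of at least 100 UMIs the adventitial median in suprabasal cells turned to 0.018.

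**Figure D3:**
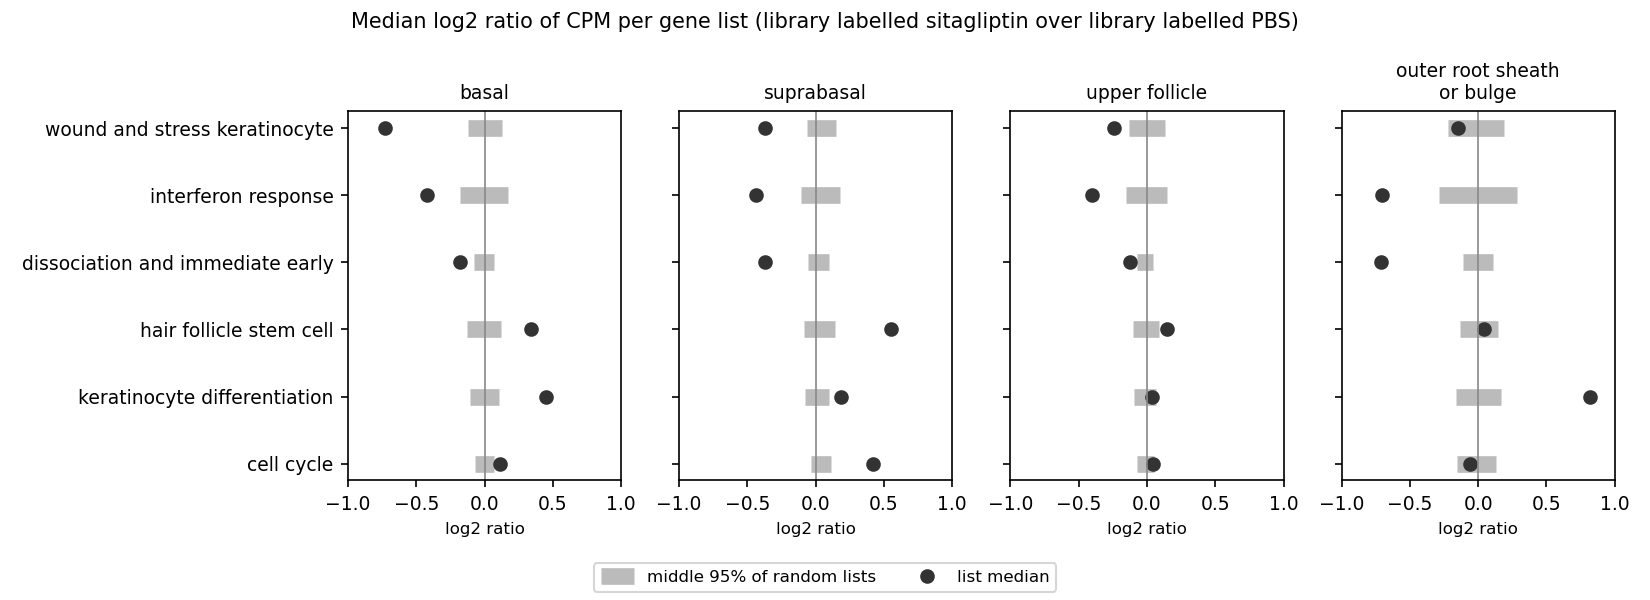
Median log2 ratio of CPM, sitagliptin-labelled over PBS-labelled library, of each gene list in the 4 keratinocyte classes (1 library per treatment); points are list medians and grey bars the central 95% of 10000 random lists matched on expression. Hair follicle stem cell genes stand at 0.55 and wound genes at -0.37 in suprabasal cells.

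Dpp4 itself, the target of sitagliptin (ENSMUSG00000035000; chromosome 2, 62330073 to 62412231, minus strand, mm10), was a fibroblast gene in this skin. In fibroblasts of the PBS-labelled library it reached 203 CPM (187 to 220.1; 596 UMIs), and 52.2% of 471 cells held a UMI at a median depth of 5465 UMIs. Macrophages, at a median depth of 4334 UMIs, held one in 3.98% of cells (8.70 CPM). T cells or innate lymphoid cells held one in 0 of 91, at a median depth of 1683 UMIs. Their upper limit of 14.1 CPM lies above the macrophage level, so absence is not shown. Lymphatic endothelial cells stood at 17.5 CPM (4.77 to 44.8), from 4 UMIs. The 9 fibroblasts of the sitagliptin-labelled library held 3 Dpp4 UMIs, too few for a comparison. Keratinocytes held few Dpp4 UMIs, whose share from free fibroblast RNA is not known: 6.56 against 9.74 CPM in suprabasal cells (ratio 0.674, 0.549 to 0.830), and 7.15 against 7.31 CPM in basal cells (ratio 0.978, 0.693 to 1.37). Ratios of 0.727 (0.387 to 1.35) in upper follicle cells and 0.773 (0.404 to 1.56) in outer root sheath or bulge cells do not separate the libraries at this depth. With free RNA subtracted at 5% of each total the ratios were 0.709 in suprabasal, 1.07 in basal and 1.05 in upper follicle cells, and as collagen RNA was lower in the keratinocytes of the sitagliptin-labelled library too, no difference in Dpp4 expression is read. The list of DPP4 family members and prolyl peptidases had medians of -0.032, -0.086, -0.0049 and -0.086 (percentiles 30.6, 5.23, 50.8 and 33.7), with Dpp8 at 48.9 against 41.3 CPM in basal cells, and genes of known DPP4 substrates, with 3 or 4 measured members, 0.17, 0.27, -0.34 and -0.36 (percentiles 88.3, 92.0, 0.450 and 3.12), with the chemokine gene Cxcl12 at 5.58 against 2.65 CPM. The upper follicle median of the substrate genes turned to 0.0026 with members of at least 100 UMIs. In upper follicle cells the Dpp4 ratio was 1.52 with at most 5% mitochondrial UMIs and 1.51 with doublets kept, and in basal cells 0.555 when thinned.

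Whether more follicle and epidermal cells were dividing, the question of follicle activation, was read from the share of cells with at least 2 of 8 mitotic genes, such as Mki67 and Top2a, after thinning every cell to 1000 UMIs. Basal keratinocytes were alike, at 36.5% (33.8 to 39.2) in the PBS-labelled and 37.0% (34.5 to 39.6) in the sitagliptin-labelled library. In suprabasal keratinocytes the share was 5.83% (4.56 to 7.34) against 12.2% (11.2 to 13.3), a ratio of 2.10 (1.62 to 2.74). Upper follicle cells stood at 19.8% (17.5 to 22.3) against 18.2% (16.6 to 19.9), and outer root sheath or bulge cells at 1.79% (0.723 to 3.65) against 2.5% (1.85 to 3.30), with intervals that overlap in each class. No cell fell under 1000 UMIs; unthinned shares were 56.3% against 52.5% in basal, 27.4% against 46.7% in suprabasal, 45.2% against 41.3% in upper follicle and 9.21% against 10.1% in outer root sheath or bulge cells. The suprabasal clusters differ between the libraries as described above, and free RNA from dividing cells stays open as a part of these shares. The suprabasal ratio was 5.15 with doublets kept, which adds only 2 cells and so acts through the clustering, and 6.61 without the 8% of cells with the highest doublet scores. In outer root sheath or bulge cells the second setting turned the ratio to 0.464. In upper follicle cells it turned to 1.09 with at most 20% mitochondrial UMIs, 1.19 with doublets kept and 1.30 with at least 3000 UMIs.

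The labels name animals of both sexes, and cells were sorted by sex-linked transcripts to see whether the libraries held different mixes. Xist, the RNA that coats the inactive X chromosome of female cells, was found without Y-linked transcripts in 92.7% (92.0 to 93.3) of retained cells in the PBS-labelled library and 78.4% (77.8 to 79.0) in the sitagliptin-labelled one, at median depths of 6900.5 and 2197 UMIs. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d gave 4 and 5 UMIs in retained cells. Cells with Y-linked and no Xist transcripts numbered 0 of 5930 and 1 of 18380. Over all barcodes Xist gave 111419 UMIs in the PBS-labelled and 101347 in the sitagliptin-labelled library. Ddx3y and Eif2s3y gave 0 in both, Uty 4 and 4, and Kdm5d 1 and 3. These counts argue against a sizeable part of male cells in either library, although the labels name both sexes.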

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

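A large group of cells that the comparisons do not use stood in the sitagliptin-labelled library. No class could be named for 41.9% of its retained cells, against 2.31% in the PBS-labelled library, and that excess over the control library is why the value is listed here. Nearly all were a cluster of 7631 cells in the sitagliptin-labelled and 41 cells in the PBS-labelled library, led by the upper follicle genes Defb6, Cst6 and Krt79 together with the epidermal genes Krt1, Krt10, Krt14 and Krtdap. These cells had a median of 1592 UMIs and held 16.3% of the UMIs of retained cells, and across genes their summed profile had a correlation of 0.997 with that of all named keratinocytes of the same library, where genes are not independent replicates. No explanation was tested for this group.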

How the results depend on the processing

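At least 3000 UMIs per cell, removal of the highest doublet scores and equal weight for clusters were chosen after the data were examined. No paired analysis was possible because each treatment has 1 library. Directions held for 299 of 299 values of the genes that met the naming rule in basal cells, 286 of 286 in suprabasal, 195 of 195 in upper follicle and 91 of 96 in outer root sheath or bulge cells. Among shares of retained cells, those of basal cells, fibroblasts and macrophages stayed lower under every setting that gave a value. Those of suprabasal cells, sebocytes and outer root sheath or bulge cells stayed higher. The suprabasal share among named keratinocytes did not, as it turned with each library scaled on its own, with doublets kept and at a Leiden resolution of 0.5. Of all values under other settings, list medians shifted by less than the spread of matched random lists in 1102 cases, moved in 248 and reversed in 10. That spread is not an error of the list median. Gene ratios stayed within their counting interval in 709 cases, moved in 213 and reversed in 5. Neither count of reversals holds every change of direction, as some were placed in the other groups. In upper follicle cells the cell cycle and differentiation medians kept their sign in 10 and 11 of 14 settings. In outer root sheath or bulge cells the cell cycle and stem cell medians did so in 8 and 7 of 13. None of these changes is among the 10, and those of Dpp4 are not among the 5. Values per setting are given for the stem cell and cell cycle lists, nearest to the series title, a restriction made after the data were examined. For the wound list medians ran over -0.97 to -0.12, -0.45 to -0.11, -0.66 to 0.18 and -0.48 to -0.084 in basal, suprabasal, upper follicle and outer root sheath or bulge cells, for interferon over -0.76 to -0.15, -0.60 to -0.13, -0.67 to -0.20 and -1.31 to -0.41, and for differentiation over 0.23 to 0.52, 0.094 to 0.31, -0.16 to 0.80 and 0.53 to 0.87. In 5 of the 6 settings that turned the upper follicle share, a large cluster of the sitagliptin-labelled library, led by Defb6 and Cst6 like the unnamed one of the main setting, took that name (43 and 7580 cells in the PBS-labelled and sitagliptin-labelled library with doublets kept, 53 and 7976 cells at resolution 0.5, 11 and 3718 cells at resolution 2, 18 and 7533 cells with separate scaling, 31 and 2284 cells at 1000 genes). Keeping called doublets adds only 2 cells, so its values show how far clusters and their names move by themselves. The 10 CPM and 3-fold rules alter counts by construction; for all other values below the cause was not tested. Cells with Y-linked transcripts alone were too few to run, and at 5% mitochondrial UMIs outer root sheath or bulge cells were too few for levels. Depth limits genes under about 10 CPM and the 391 outer root sheath or bulge cells of the PBS-labelled library.

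Below, outer sheath stands for outer root sheath or bulge. At most 5% mitochondrial UMIs gave share ratios of 1.24 for suprabasal, 0.794 for upper follicle, 0.487 for basal, 5.09 for outer sheath, 16.9 for sebocyte and 0.00554 for macrophage cells and 24 in suprabasal and 20 in basal cells as the number of genes past the size rule. Medians of 0.10 in suprabasal and -0.32 in upper follicle cells for the cell cycle list followed. Gene ratios were 1.52 for Dpp4 in upper follicle cells. At least 1000 genes and 2000 UMIs per cell gave share ratios of 1.61 for suprabasal, 1.95 for upper follicle, 0.556 for basal, 2.60 for sebocyte and 0.0532 for fibroblast cells and 17 in upper follicle cells as the number of genes past the size rule. Medians of 0.39 in suprabasal cells for the stem cell list, 0.22 in suprabasal, -0.047 in upper follicle, 0.18 in basal and 0.38 in outer sheath cells for the cell cycle list, 0.10 in upper follicle cells for the wound list, 0.062 in outer sheath cells for the Hedgehog list and 0.0091 in outer sheath cells for the angiogenesis list followed. Gene ratios were 2.01 for Dct in outer sheath, 3.63 for Nrp2 in outer sheath and 1.05 for Slc7a2 in outer sheath cells. Keeping called doublets gave share ratios of 1.21 for suprabasal, 2.68 for upper follicle and 0.0241 for fibroblast cells and 34 in suprabasal and 33 in upper follicle cells as the number of genes past the size rule. Medians of 1.11 in suprabasal and 0.044 in upper follicle cells for the stem cell list, 1.15 in suprabasal and -0.12 in upper follicle cells for the cell cycle list and 0.18 in upper follicle cells for the wound list followed. Gene ratios were 1.51 for Dpp4 in upper follicle cells, and ratios of dividing cells 5.15 in suprabasal and 1.19 in upper follicle cells. At least 3000 UMIs per cell gave share ratios of 1.82 for suprabasal, 1.47 for upper follicle, 0.626 for basal, 2.76 for outer sheath, 1.58 for sebocyte, 0.0189 for fibroblast and 0.00624 for macrophage cells. Medians of 0.31 in suprabasal and -0.20 in outer sheath cells for the stem cell list, 0.20 in suprabasal, 0.24 in basal and 0.43 in outer sheath cells for the cell cycle list and 0.075 in upper follicle cells for the wound list followed. Gene ratios were 3.06 for Nrp2 in outer sheath and 1.20 for Slc7a2 in outer sheath cells, and ratios of dividing cells 1.30 in upper follicle and 1.21 in basal cells. Removing the 8% highest doublet scores gave share ratios of 1.57 for suprabasal and 1.39 for outer sheath cells and 38 in suprabasal and 37 in outer sheath cells as the number of genes past the size rule. Medians of 1.30 in suprabasal cells for the stem cell list and 1.13 in suprabasal, 0.12 in upper follicle and -0.62 in outer sheath cells for the cell cycle list followed. Ratios of dividing cells were 6.61 in suprabasal and 0.464 in outer sheath cells. Leiden resolution 2 gave share ratios of 1.98 for suprabasal, 1.96 for upper follicle, 0.0276 for fibroblast and 0.00421 for macrophage cells. Scaling each library on its own gave share ratios of 1.02 for suprabasal, 2.44 for upper follicle, 0.479 for basal, 1.40 for outer sheath, 0.0864 for fibroblast and 0.0327 for macrophage cells. Counting within the broad class gave share ratios of 1.30 for suprabasal, 0.717 for upper follicle, 0.433 for basal, 1.85 for outer sheath and 0.467 for macrophage cells. Keeping cells with Xist alone gave share ratios of 1.23 for suprabasal, 0.530 for upper follicle and 1.35 for outer sheath cells. Leiden resolution 0.5 gave share ratios of 2.79 for upper follicle, 0.418 for basal and 0.0472 for fibroblast cells. At most 20% mitochondrial UMIs gave share ratios of 1.06 for outer sheath, 0.0510 for fibroblast and 0.00580 for macrophage cells and 30 in outer sheath cells as the number of genes past the size rule. Medians of -0.47 in outer sheath cells for the cell cycle list followed. Ratios of dividing cells were 1.09 in upper follicle cells. The mean of each cell's CPM gave 34 in suprabasal cells as the number of genes past the size rule. Medians of 1.02 in suprabasal cells for the stem cell list and 0.65 in suprabasal and 0.10 in outer sheath cells for the cell cycle list followed. Thinning to 1000 UMIs gave 45 in suprabasal, 15 in upper follicle and 21 in basal cells as the number of genes past the size rule. Medians of 1.28 in suprabasal, 0.015 in basal and -0.12 in outer sheath cells for the stem cell list and 0.67 in suprabasal, -0.052 in upper follicle and 0.020 in basal cells for the cell cycle list followed. Gene ratios were 0.555 for Dpp4 in basal cells. Weighting clusters equally gave 7 in suprabasal and 31 in outer sheath cells as the number of genes past the size rule. Medians of 0.16 in suprabasal and 0.10 in outer sheath cells for the cell cycle list, 0.038 in outer sheath cells for the Hedgehog list and -0.10 in outer sheath cells for the stem cell list followed. A minimum of 10 CPM gave 54 in suprabasal, 36 in upper follicle, 48 in basal and 265 in outer sheath cells as the number of genes past the size rule. A 3-fold rule gave 2 in suprabasal, 1 in upper follicle, 1 in basal and 16 in outer sheath cells as the number of genes past the size rule. A pseudocount of 10 CPM gave medians of 0.40 in suprabasal and 0.14 in basal cells for the stem cell list and 0.31 in suprabasal cells for the cell cycle list. List members with at least 100 UMIs gave medians of 0.018 in suprabasal cells for the adventitial fibroblast list, 0.0026 in upper follicle cells for the DPP4 substrate list, 0.18 in basal cells for the stem cell list, 0.17 in outer sheath cells for the extracellular matrix list and 0.15 in outer sheath cells for the macrophage list.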

Other observations

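The tests on fibroblasts, the depth test on genes apart in all 4 classes, the ranges of the clock difference and the tests of shared reads by gene were chosen after the results were seen, and the clock and other glucocorticoid lists were added after Tsc22d3, Fkbp5 and Zbtb16 had been seen to differ. Dermal and immune cells of the PBS-labelled library, which the comparison leaves without a partner, are described for that library alone, and the part of each level that free RNA carries is not known. Fibroblasts, 471 cells, expressed the adventitial genes Ly6a at 2875 CPM (2814 to 2937), Fbn1 at 1697 CPM and Clec3b at 1449 CPM, next to Dpp4. They also held genes of DPP4 substrates, Igf1 at 378 CPM (356 to 401), the chemokine genes Cxcl12 at 307 CPM and Ccl11 at 142 CPM, and the Wnt inhibitor gene Sfrp4 at 479 CPM (454 to 504). Fap, the closest relative of Dpp4, stood at 72.6 CPM in them, and the TAM receptor ligand gene Gas6 at 1283 CPM.

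Macrophages or monocytes, 1030 cells, held genes of tissue-resident and repair macrophages, with the coagulation factor gene F13a1 at 1596 CPM (1563 to 1628), the mannose receptor gene Mrc1 at 1369.5 CPM and Ccl8 at 1277 CPM. The class borders on dendritic cells, as 340 PBS-labelled cells of a cluster led by H2-Aa, H2-Ab1, Cd74 and Retnla were left unnamed at a Leiden resolution of 2. The chemokine genes Ccl7, Cxcl2 and Ccl2 stood at 309 CPM, 219 CPM and 218 CPM, and the prolyl peptidase gene Prcp at 174 CPM. Dendritic cells, 86 cells, held the DPP4 substrate gene Ccl22 at 48.8 CPM.

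The few fibroblasts and macrophages of the sitagliptin-labelled library were weighed first. Among cells with at least 3000 UMIs there were still 0.0302 (0.0144 to 0.0561) times as many fibroblasts per basal keratinocyte (10 to 959 against 384 to 1112), which argues against dilution by low-UMI barcodes as the whole cause. Over all barcodes without any filter the summed fibroblast markers came to 0.910 of the PBS-labelled level, but Apoe, which other skin cells express, made up 84.1% of that sum (6345 against 5064 CPM), so a second test was chosen after that value, the median marker, which came to 0.0208 with 13 of 16 markers under the bound and argues against loss by filters or cluster names. Collagen RNA in basal keratinocytes was 0.0781 (0.0478 to 0.121) of the PBS-labelled level (2.55 against 32.6 CPM), as a suspension with fewer dermal cells may give. Whether dissection, dissociation, the treatment or exchanged labels lies behind this cannot be told apart with 1 library per treatment.

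A set of genes differed in the same direction by at least 1.5-fold in all 4 main classes, 21 higher and 3 lower of 2312 considered; the higher ones, with Nmt1, Tsc22d3, Dync1i2, Nmt2, Zbtb16, Txnip, Btg1 and mt-Atp8 among them, and the lower ones, Hspa1a, Hbegf and Rpl10, were picked by this size alone. Genes with most of their 3' end words in another gene were 4.76% of the higher genes (1 of 21, Rps27rt, with 92.4%), within the 9.52% that matched random sets reach, and although others shared some (Wdr89 26.4%, Btg1 20%, Nsa2 18.1%), Nmt1, Nmt2, Zbtb16 and mt-Atp8 shared 0%, which argues against shared reads as the cause of the whole set. Of the 3 lower genes 0 had most of their 3' end words in another gene, a count too small against the 33.3% of random sets to decide for the set, but by gene Hspa1a and Hbegf shared 0%, which argues against shared reads for these 2, and Rpl10 shared 41.3%, which leaves them open for it. With at least 3000 UMIs per cell the higher genes kept 88.9% or more of their median log2 ratio in each class. This cannot decide on depth, as the PBS-labelled cells of that setting were still deeper. Their median was 8247 against 6407 UMIs over all cells and 6678 against 4239 in the largest basal cluster. A difference between the 2 preparations and an effect of sitagliptin may each give such a set and cannot be told apart here, and the biological explanation was not tested.

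Tsc22d3, Fkbp5 and Zbtb16, glucocorticoid-responsive genes, were higher in the 4 classes, and a candidate explanation is a wider glucocorticoid response in the sitagliptin-labelled library. Of 4 main classes, 4 had the median of other glucocorticoid-responsive genes in the highest 2.5% of matched random lists, with percentiles of 98.2 in basal, 99 in suprabasal, 100 in upper follicle and 100.0 in outer root sheath or bulge cells and medians of 0.15 to 0.34, although 0 of 14, 0 of 16, 3 of 15 and 4 of 14 members were at least 1.5-fold higher in these classes in that order and 0, 1, 0 and 1 lower. Another time of day at collection would part clock output genes from clock activators, and the difference of their medians was -0.33 over the classes, short of the bound of 0.6 but negative in each, at -0.34 (-0.60 to -0.020), -0.16 (-0.58 to -0.041), -0.31 (-0.62 to 0.034) and -0.52 (-1.86 to -0.20) with 95% ranges over members drawn again, so a shift in time stays open. Within the PBS-labelled library the cells lowest in immediate early genes had at most 0.998 times the level of the first 3 genes in the cells highest in them, where lower dissociation stress as the cause needs 1.5 times. Handling or wound stress that differed between the preparations, the treatment, and exchanged labels stay open too.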
